A study of Caenorhabditis elegans with 2 samples.

How the data were processed

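The samples are 2 biological replicates of anti-GFP ChIP-seq on whole young adults, 64 hours old, of a Caenorhabditis elegans strain whose ceh-100 gene carries a TY1, EGFP and FLAG tag. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp. The authors aligned reads to ce11 and called peaks with the ENCODE processing for transcription factors. The aligner, the peak caller and their versions are not given in the sources used here. Per the deposited text lists, each replicate's peaks derive from its own alignment and a control alignment, and the joint lists derive from the alignments of both replicates, a control alignment and 1 further input whose content is not described.

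The signal value of each peak is the authors' peak caller enrichment value, with no unit and not scaled between lists. The score in the deposited peak lists is the authors' scaled irreproducible discovery rate (IDR) score, at most 1000 and at least 830 in the thresholded lists. The ranked lists give the authors' −log10 of the global IDR per peak, limited to 5. The joint ranked list also carries the signal of the matching peak in each replicate. The 2 such columns of the pooled pseudoreplicate list were not used. No read counts are given, so the depth of each library is unknown and no result could be adjusted for it. Shares of peaks or genes have 95% Wilson intervals, which cover counting error only.

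The lists hold 1182 and 1360 thresholded peaks and 25241 and 17118 ranked peaks for replicates 1 and 2, 1707 in the conservative set and 1911 in the authors' other thresholded set, which can use pooled pseudoreplicates. The ratio of the replicates' peak numbers was 1.15 and that of the other set to the conservative set 1.12. Summits were taken from the lists. In the conservative set, 12 peaks share an interval with another peak and differ in summit. Peaks on the mitochondrial genome, 22 in the conservative set, were left out of all results on nuclear chromosomes. Annotation was Ensembl release 115 on WBcel235, which has the chromosome lengths of ce11, with 19973 protein-coding genes and 29784 distinct protein-coding starts on 6 nuclear chromosomes.

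The following choices were made before the data were examined: the tests, the 30 gene lists, the windows, most alternatives and the rule for named genes. Sharing between replicates was overlap of at least 1 bp, tested against 1000 circular shifts (one-sided permutation test). Correlations of signal are Spearman's rho, with an interval from 1000 bootstrap draws of peaks, and Pearson's r of log2 values. The share of summits within 500 bp of a start was tested against 1000 sets of random positions on the same chromosomes. The features under summits and the peaks per chromosome were tested with two-sided exact binomial tests, and the gene lists with two-sided Fisher's exact tests of members against all other protein-coding genes. A gene had a peak when a summit lay within 500 bp of any of its starts, so 1 peak can count for several genes. Non-coding classes used summits within 250 bp of a gene and 1000 random sets. TAATTA and all 2080 6-mers, merged with their reverse complements, were counted in 101 bp windows at summits and in flanking windows centred 300 bp away, with two-sided exact McNemar tests. Benjamini-Hochberg adjustment was made within each family, at 0.05. All random draws used seed 1. These p-values describe the peaks of these lists. They do not measure spread between animals, since a single group of 2 replicates is present, and no comparison between conditions was made.

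Named genes followed a rule: ceh-100, the genes at the 25 peaks of highest signal within 500 bp of a start, up to 4 members of each called list and 2 of each other list by signal, the 5 peaks of highest signal over 2000 bp from a start, the 5 peaks of highest signal per replicate without a match in the other ranked list, and the 5 6-mers of lowest p among those more frequent at summits. Some genes with a peak are not reported here. Alternatives were the other thresholded set, a global IDR of at most 0.01, each replicate's own list, peaks beside tRNA, rRNA, snRNA and snoRNA genes left out, other overlap rules, other window sizes, random positions within 10000 bp, chromosome length, only the nearest gene per peak, 10000 permutations within chromosome and position class, other background windows and TAAT or ATTA in place of TAATTA. Because an IDR of 0.01 equals the authors' threshold, 0.001 was added after the data were seen. Also added then were pairs thresholded in both replicates, shuffled windows, left-out ranked peaks put back and peaks with a repeated 31-mer left out. In the same way, 10 further gene lists were added, whose results are given once under the other observations.

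Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. With 71.96% planted sharing, 73.5% was recovered, at a permutation p of 0.0099, and an unrelated set gave 0.644. Of lists given a 3-fold chance of a peak, 62% were called, and 0% of unchanged lists were called enriched. A 6-mer planted in some windows ranked 1 among 2080, with 6 called, and 0 were called without planting. Both sets of windows were drawn at random from the genome. This test therefore does not cover the difference in base composition between summits and flanks.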

Results

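The data are chromatin immunoprecipitation and sequencing (ChIP-seq) peaks of CEH-100, a homeobox protein of Caenorhabditis elegans, in whole young adults. The strain, RW12233, carries an insertion made with CRISPR at the endogenous ceh-100 gene, so that the protein ends in TY1, EGFP and FLAG tags, and chromatin was precipitated with an antibody against GFP. All animals belong to 1 group of 2 biological replicates, 64 hours old, grown from synchronised first-stage larvae. Positions are those of the ce11 assembly. The authors' thresholded lists hold 1182 peaks for replicate 1 and 1360 for replicate 2, of which 1166 and 1333 lie on the 6 nuclear chromosomes. Most results rest on the conservative set, in which peaks had to be reproducible between both replicates. It holds 1707 peaks, 1685 of them nuclear, with a median width of 316 bp. Signal is the authors' enrichment value per peak, without a unit. In the conservative set it ranged from 2.01 to 6296, with a median of 135. The files give no read counts, so the depth of each library is unknown. With a single group there is no comparison between conditions, and the questions are where the tagged protein's peaks lie and how far the replicates match.

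The peaks of highest signal among those within 500 bp of a protein-coding start are described first, so that their place near genes follows from how they were chosen. The highest was at eel-1, which encodes a HECT-type ubiquitin ligase (WBGene00022069, chromosome IV, 3050258 to 3050747). Its summit lay in intergenic sequence 375 bp upstream of the annotated start. Its signal was 6296, with 3055 in replicate 1 and 3439 in replicate 2. A peak with a signal of 4443 lay in an intron of the centrosome scaffold gene spd-5, 237 bp from its start and 412 bp upstream of the start of npp-6, a nuclear pore gene on the other strand (chromosome I, 5176026 to 5176606). The ribosomal protein gene rps-24 followed with 4027 (chromosome IV, 385052 to 385748) and the chaperone cofactor gene bag-1 with 3822 (chromosome I, 6564414 to 6564846). Signals were 3759 at mtcu-2, 3701 at ecps-1, 3643 at the mitochondrial ATPase gene atad-3 and 3537 at dnj-28, whose opposite-strand neighbour supr-1 also starts within 500 bp. The pair F29B9.11 and jmjd-1.2 had 2605. The pair lin-35, the retinoblastoma homologue, and vps-51 also had 2605 (chromosome I, 5807185 to 5807713). Signal was 2471 at W03C9.5. The peak of snx-13 and snr-1, a core spliceosomal gene, had 2440 (chromosome IV, 17087341 to 17087816). The remaining 13 named peaks had signals from 1671 to 2324. They lie at atx-2, ash-2 with Y17G7B.20, C26B2.7, Y41D4A.4 with Y41D4A.6, czw-1 with F20D12.12, K10D2.5, zipt-9, rae-1, cept-2, ubc-6 with aka-1, eif-3.E, C13B4.1 and Y50D4C.5. All 25 of these peaks passed the threshold in both replicates. Of the 25 summits, 24 lay upstream of the nearest start and 22 in intergenic sequence. None was on X. The signals of the replicates differed by at most 1.75 times, at ash-2. These 25 are not the 25 highest nuclear peaks: by signal the peak at eel-1 ranked 1, that at spd-5 ranked 4 and that at Y50D4C.5 ranked 32. Peaks of high signal between 500 and 2000 bp from a start fall under no naming rule and are not reported here.

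The ceh-100 gene itself carried no peak within 500 bp of its start. The nearest conservative peak (chromosome II, 12604320 to 12604635) had its summit 798 bp upstream of the ceh-100 start at 12603680. That summit lay 92 bp from the start of the neighbouring gene lips-15, at 12604386. Its signal of 108.9 ranked 1214 among 1707, with a global irreproducible discovery rate (IDR) of 0.00091. Replicate 2 had the peak in its thresholded list, with a signal of 61.8. In replicate 1 it was present in the ranked list only, with a signal of 56.3 and a global IDR of 0.0589.

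The replicates shared most of their peaks. Of the 1166 nuclear peaks of replicate 1, 904 (77.5%, 95% Wilson interval 75.05 to 79.8) overlapped a thresholded peak of replicate 2. In the other direction, 891 of 1333 (66.8%, 64.3 to 69.3) overlapped. Shifting the other replicate's peaks along the chromosomes gave means of 0.763% and 0.674% in the same order (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Sharing followed signal. Of the 234 replicate 1 peaks of highest signal, 100% were shared, against 44.6% of the 233 of lowest signal. For replicate 2 the same shares were 99.3% of 267 and 34.2% of 266. Against the other replicate's whole ranked list, 97.9% and 96.6% of thresholded peaks had a match, where shifted peaks gave means of 9.62% and 13.8%. Among the peaks of lowest signal, 92.3% in replicate 1 and 91.7% in replicate 2 had such a match. Most weak peaks were thus present in the other replicate, though often under its threshold. Spearman's rho of signal across 1579 pairs of overlapping peaks was 0.685 (95% bootstrap interval 0.650 to 0.718), and Pearson's r of log2 signal was 0.838. A replicate 2 peak can enter several pairs, and 676 pairs passed the threshold in 1 replicate only. These values are across peaks, which are not independent replicates.

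**Figure D1:**
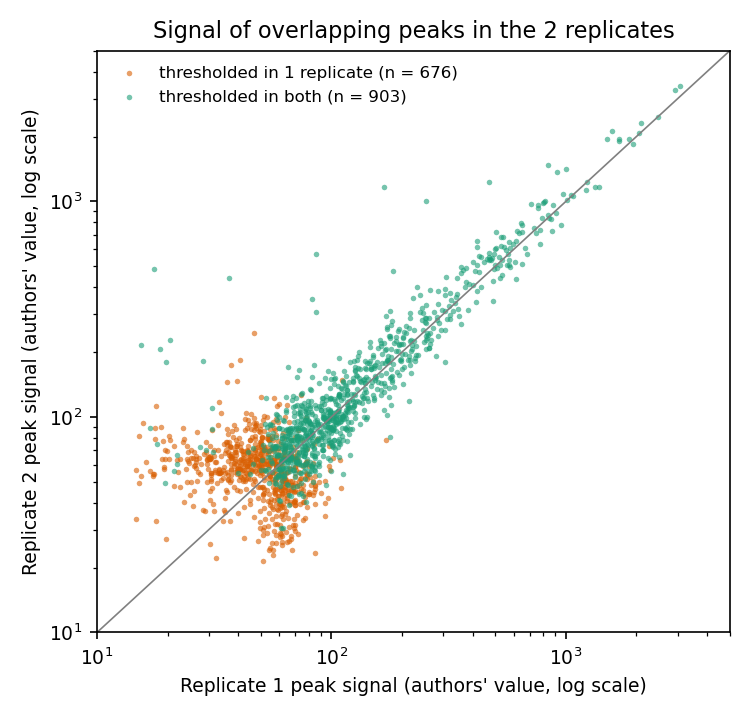
Signal of overlapping peaks in replicate 1 (x axis) and replicate 2 (y axis), the authors' value without a unit, both axes on a log scale. Each point is a peak pair, coloured by whether both replicates (903 pairs) or 1 replicate (676 pairs) passed the threshold, and the grey line marks equal signal. A replicate 2 peak can be in several pairs. Spearman's rho over all 1579 pairs is 0.685, and pairs that passed in both replicates have a rho of 0.841.

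Peaks lay at annotated transcript starts more often than random positions did. A start here is the annotated 5' end of a protein-coding transcript, and measured transcription starts were not used. Of the 1685 nuclear summits, 943 (56.0%, 53.6 to 58.3) were within 500 bp of an annotated protein-coding start. Random positions on the same chromosomes gave a mean of 23.3% and a maximum of 26.8% (ratio 2.40, one-sided permutation p = 0.001). Of those 943 summits, 758 (80.4%, 77.7 to 82.8) were upstream of the nearest start, and 236 (25.03%, 22.4 to 27.9) also had a start on the opposite strand within 500 bp. Intergenic sequence held 1083 summits (64.3%, against 35.4% expected from its length, adjusted exact p = 1.08e-126, two-sided exact binomial test). The 5' untranslated regions held 72 (4.27% against 1.42%, adjusted exact p = 1.44e-15). Introns held 373 (22.1% against 34.4%, adjusted exact p = 8.55e-28) and coding exons 95 (5.64% against 25.21%, adjusted exact p = 4.35e-100). The share in 3' untranslated regions, 3.44%, did not differ detectably from the 3.38% expected (adjusted exact p = 0.84).

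A smaller group of 281 summits (16.7%) lay over 2000 bp from any protein-coding start. The 5 of highest signal were nearest to efa-6 (chromosome IV, 12621713 to 12622036, signal 1469, 7148 bp from the start), K08F11.1 (chromosome IV, signal 1037, 2900 bp), goa-1, a G protein alpha subunit gene (chromosome I, 7518901 to 7519200, signal 1027, 3058 bp), F58D12.3 (chromosome V, signal 832, 2547 bp) and K07C11.10 (chromosome V, signal 566, 2123 bp). The last of these lay in an intron of rol-3. All 5 passed the threshold in both replicates. The peaks nearest to goa-1 and K07C11.10 also lie within 250 bp of a small RNA gene.

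Chromosomes I and III held more peaks than their share of protein-coding starts, and V and X held fewer. On X there were 128 peaks against 234.7 expected, an observed over expected ratio of 0.545 (95% Wilson interval 0.461 to 0.643, adjusted exact p = 1.45e-15, two-sided exact binomial test). Chromosome V had 250 peaks and a ratio of 0.626 (0.558 to 0.701, adjusted exact p = 8.03e-19). Ratios were 1.56 on chromosome I, with 389 peaks (1.43 to 1.70, adjusted exact p = 8.03e-19), and 1.43 on III, with 320 peaks (1.29 to 1.57, adjusted exact p = 1.1e-10). Chromosomes II and IV did not pass the test, with ratios of 1.06 (adjusted exact p = 0.288) and 1.01 (adjusted exact p = 0.873). Leaving out peaks beside tRNA, rRNA, snRNA and snoRNA genes lowered the ratio on X to 0.312.

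**Figure D2:**
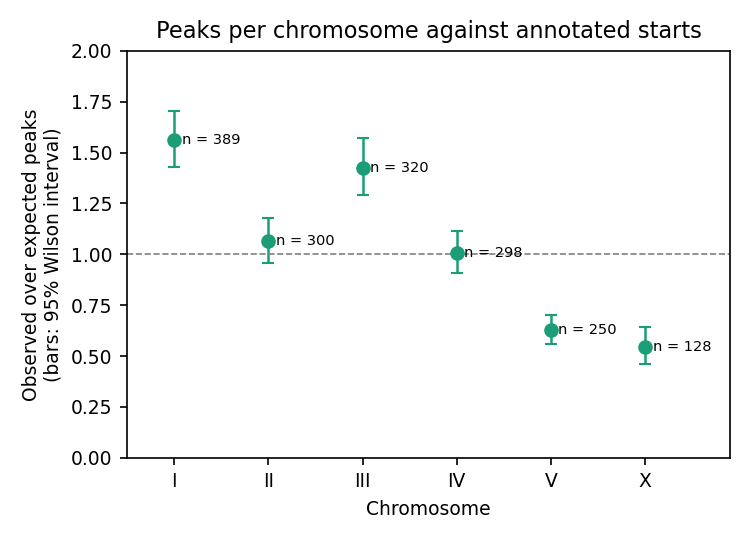
Observed over expected number of conservative-set peaks (y axis, ratio without a unit) on each nuclear chromosome (x axis), with the expectation from annotated protein-coding starts. Points are ratios with their number of peaks, bars are 95% Wilson intervals and the dashed line marks 1. X lies at 0.545 and V at 0.626, while I lies at 1.56 and III at 1.43.

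Genes of the ribosomal protein, translation factor, splicing factor and respiratory chain lists carried peaks at their starts more often than other genes. Over all protein-coding genes, 1110 of 19973 (5.56%) had a summit within 500 bp of a start. Of 81 ribosomal protein genes, 47 had a peak (58.0%, odds ratio 24.5, 95% interval 15.3 to 39.4, adjusted exact p = 1.48e-36, two-sided Fisher's exact test with adjustment over 30 lists). Signal was 1004 at rpl-35, 970.1 at rpl-3 and 785 at rpl-15, beside rps-24 above. Translation factors had peaks at 10 of 39 genes (25.6%, odds ratio 5.903, adjusted exact p = 0.000141). Among them were eif-3.E with a signal of 1712, eif-3.C with 418, iff-2 with 403 and eef-1G with 200.9. Of 39 splicing factor genes, 13 had a peak (33.3%, odds ratio 8.58, adjusted exact p = 7.42e-07), which were 12 distinct peaks since rsp-1 and rsp-2 share a peak. The examples of highest signal were snr-1, snr-2 with 572, snr-4 with 297 and hrpk-1 with 288. The mitochondrial respiratory chain and ATP synthase list had 13 of 49 (26.5%, odds ratio 6.20, adjusted exact p = 1.09e-05), with cox-5A at 539, cox-5B at 419.9, atp-1 at 243 and cyc-1 at 232. These 4 lists kept their calls under all 10 alternatives, but the size of the ribosomal result rested on the window. With a 200 bp window 9 of the 81 ribosomal protein genes had a peak (odds ratio 4.19, adjusted exact p = 0.00298), and with only the nearest gene per peak 33 did (odds ratio 15.5).

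Protein turnover and folding genes followed. The proteasome list had 8 of 33 genes with a peak (24.2%, odds ratio 5.47, adjusted exact p = 0.000886), among them pbs-3 with a signal of 649, rpn-3 with 212, rpt-1 with 164 and rpn-9 with 145.01. Chaperone and heat shock genes had 14 of 60 (23.3%, odds ratio 5.22, adjusted exact p = 1.94e-05), with dnj-28 first, then dnj-13 with 640.3, dnj-12 with 605 and cct-8 with 519. The call for the proteasome ended at a stricter IDR (odds ratio 2.54, adjusted exact p = 0.192). That for chaperones ended with a 200 bp window (odds ratio 1.75, adjusted exact p = 0.367) and with only the nearest gene per peak (odds ratio 2.43, adjusted exact p = 0.0828). The V-ATPase list had 4 of 21 (19.05%, odds ratio 4.01, adjusted exact p = 0.0399), namely vha-1 with 204, vha-18 with 195, vha-9 with 170.2 and vha-8 with 92.3. Its call ended under 6 of the 10 alternatives, with the odds ratio at 0 for a 200 bp window and a highest adjusted p of 1.

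Chromatin, cell division and nuclear pore genes were also above the rest. The DREAM and synMuv chromatin factors, repressors that include the worm retinoblastoma complex, had 8 of 23 (34.8%, odds ratio 9.12, adjusted exact p = 8.81e-05). After lin-35, signals were 439.7 at lin-61, 388 at lin-53 and 359 at lin-54. Cell cycle and replication genes had 6 of 36 (16.7%, odds ratio 3.41, adjusted exact p = 0.0213). The 4 of highest signal were bub-1, in the same peak as lin-61, pcn-1 with 249, mcm-2 with 225 and mcm-4 with 171. Nuclear pore genes had 6 of 26 (23.1%, odds ratio 5.12, adjusted exact p = 0.00591), with npp-6 first, then npp-8 with 436, npp-3 with 377 and npp-1 with 263. Without replicate 1 its odds ratio was 8.70. With a 200 bp window the DREAM and synMuv call ended (odds ratio 4.99, adjusted exact p = 0.0573), and the odds ratio of the cell cycle list was 0.947 (adjusted exact p = 1). Permuting within chromosome position classes ended the calls for the nuclear pore list (adjusted permutation p = 0.0555) and the cell cycle list, whose call also ended in the authors' other thresholded set.

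Germline, small RNA and metabolic lists were above other genes too. Germline and oocyte genes had 11 of 57 with a peak (19.3%, odds ratio 4.09, adjusted exact p = 0.000707), with signals of 324 at the germ granule helicase gene glh-1, 269 at glh-2, 249 at syp-4 and 195 at pos-1, in the peak also assigned to vha-18. The small RNA pathway list had 11 of 78 (14.1%, odds ratio 2.81, adjusted exact p = 0.00756), with 1463 at mut-15, 1237 at tofu-1, 1013 at nrde-4 and 464 at nrde-2. Its name pattern also caught 13 algn genes, which encode glycosylation enzymes, and without them 9 of 65 genes had a peak (odds ratio 2.75, exact p = 0.00948). The insulin, TOR and autophagy list had 6 of 32 (18.8%, odds ratio 3.94, adjusted exact p = 0.0134), with 173 at ragc-1, 173 at atg-3, 128 at atg-9 and 122 at lgg-2. Glycolysis and TCA cycle genes had 6 of 35 (17.1%, odds ratio 3.53, adjusted exact p = 0.0197), with 271 at pck-2, 163 at aco-2, 138 at gpi-1 and 129 at hxk-2. The germline call ended with a 200 bp window (odds ratio 2.51, adjusted exact p = 0.142) and the small RNA call with the permutation within position classes (adjusted permutation p = 0.0565). The insulin list lost its call under 4 alternatives (highest adjusted p of 0.117) and the glycolysis list under 3 (highest adjusted p of 0.103). Over all 10 alternatives their odds ratios, or folds in the permutation, were 2.86 to 4.30 and 2.80 to 4.30.

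Genes of the chemoreceptor, nuclear hormone receptor, F-box, innate immunity, detoxification and neuropeptide lists had peaks less often than other genes. Of 1277 genes on the chemoreceptor list, 5 had a peak (0.392%, odds ratio 0.0626, adjusted exact p = 1.26e-24): sri-5, srh-269, srh-16, srw-95 and srrt-1. The last is named only because the count is small, and whether srrt-1 encodes a chemoreceptor was not checked. Nuclear hormone receptors had 2 of 274 (0.73%, odds ratio 0.1234, adjusted exact p = 0.000141), nhr-47 with a signal of 194 and nhr-41 with 115. F-box, MATH and BTB genes had 3 of 432 (0.694%, odds ratio 0.116, adjusted exact p = 7.42e-07), namely fbxb-85 with 616, bath-36 with 116.2 and skr-18 with 115.9. Innate immunity genes had 3 of 312 (0.962%, odds ratio 0.163, adjusted exact p = 0.000141), namely clec-126, clec-57 and clec-87. Detoxification genes had 2 of 188 (1.06%, odds ratio 0.181, adjusted exact p = 0.00717), gst-27 and cyp-14A4. Neuropeptide genes had 1 of 144, nlp-4 (0.694%, odds ratio 0.118, adjusted exact p = 0.00965), and this call ended at a stricter IDR and with a 200 bp window (highest adjusted p of 0.213). Over the 10 alternatives the odds ratios, or folds in the permutation, moved by over 1.5 times in the other 5 families, from 0.0428 to 0.104 for chemoreceptors, 0.0661 to 0.213 for nuclear hormone receptors, 0.0577 to 0.236 for F-box, MATH and BTB genes, 0.0579 to 0.247 for innate immunity and 0 to 0.234 for detoxification. Without replicate 1 they were 0.213 for nuclear hormone receptors, 0.224 for F-box, MATH and BTB genes, 0.0616 for innate immunity, which had 0.0732 without replicate 2, and 0.103 for detoxification.

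The other lists, most of them of tissues, did not pass the test in either direction, although histones and collagens passed under some alternatives. No peak was found at the starts of 49 neuronal genes (95% upper limit 7.27%), 24 pharynx genes (13.8%), 35 intestine genes (9.89%) or 17 hypodermis regulators (18.4%). These 0 counts were not all stable: without replicate 2, that is in replicate 1's own list, 2 neuronal genes had a peak (odds ratio 0.984, adjusted exact p = 1), and in the authors' other thresholded set 1 neuronal gene and 1 hypodermis regulator did (odds ratios 0.32 and 0.962). With a 1000 bp window 1 intestine gene had a peak (odds ratio 0.374). Body wall muscle had 1 of 34, act-2 with a signal of 151. Collagens and cuticle genes had 6 of 184 (adjusted exact p = 0.247), with col-2 at 997 and col-85 at 208, and fell below other genes with a 200 bp window, where none had a peak (adjusted exact p = 0.0181). Homeobox genes, the family of ceh-100, had 2 of 100 (odds ratio 0.346, adjusted exact p = 0.238), ceh-38 with 130.3 and ceh-43 with 123.3. Sperm genes had 4 of 93 (adjusted exact p = 0.848), with spe-48 at 266 and spe-39 at 132, and an odds ratio of 0.763 that was 0.426 without replicate 1 and 0.507 without replicate 2. Signalling genes had 4 of 133 (adjusted exact p = 0.303), with lin-3 at 656 and wrt-3 at 135, and with dsl-6 and grl-26 also named after the values were known. Histone genes had 8 of 72 in 6 distinct peaks (11.1%, adjusted exact p = 0.0886), with his-67 and his-68 sharing a peak of signal 264. They passed as above other genes with a 1000 bp window (15 genes, odds ratio 3.38, adjusted exact p = 0.000482), without replicate 2 (odds ratio 2.91, adjusted exact p = 0.0176) and with peaks beside tRNA, rRNA, snRNA and snoRNA genes left out (odds ratio 2.30, adjusted exact p = 0.0462). Over the 30 lists, 14 were above other genes, 6 below and 10 not called. With a 200 bp window 585 genes had a peak and 8 lists were above, and with permutation within position classes 9 were.

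**Figure D3:**
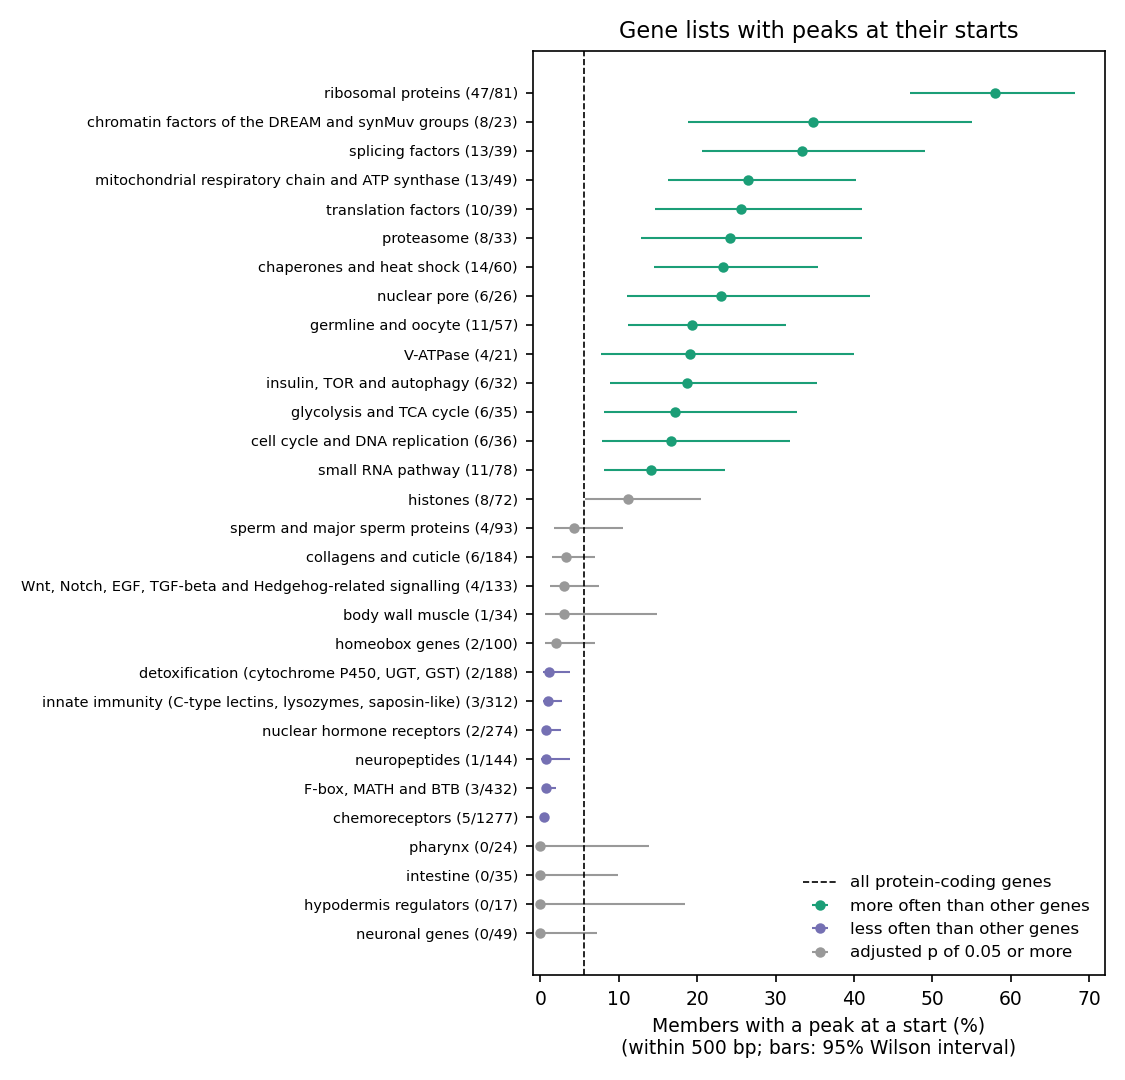
Percent of each list's members with a conservative-set summit within 500 bp of a start (x axis) for the 30 gene lists (y axis, with members with a peak and all members). Points are percentages, bars are 95% Wilson intervals, colours give the call after adjustment and the dashed line marks the 5.56% of all protein-coding genes. Ribosomal protein genes stand at 58.0% and chemoreceptors at 0.392%.

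Genes for tRNAs and several other classes of short RNA had summits beside them far more often than chance gave. Within 250 bp of a tRNA gene lay 172 summits (10.2%), against a mean of 4.39 among random positions (ratio 39.1). For snRNA genes there were 44 summits (ratio 30.4), for snoRNA genes 90 (ratio 22.6) and for miRNA genes 10 (ratio 4.52). All 4 classes had an adjusted p of 0.0015 (one-sided permutation test over 6 classes). Peaks lay at 187 of 612 tRNA genes (30.6%), 39 of 129 snRNA genes (30.2%), 86 of 346 snoRNA genes (24.9%) and 10 of 261 miRNA genes (3.83%). Genes for piRNAs, which are clustered on chromosome IV, had 25 summits against 62.7 at random (ratio 0.399), a direction that the one-sided test does not address. No summit was found within 250 bp of the 20 rRNA genes, where random positions gave a mean of 0.357. Against random positions within 10000 bp of each summit the ratios were 14.9, 11.2, 9.33 and 2.78 for tRNA, snRNA, snoRNA and miRNA genes. Counting only summits inside the gene gave ratios of 176 for tRNA genes (108 summits), 58.1 for snRNA genes (18) and 24.5 for snoRNA genes (21). For miRNA genes the ratio was 8.04, but it rested on 3 summits, where random sets held up to 4.

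The sequence TAATTA, a common core of homeodomain binding sites, was rarer at summits than beside them. It occurred in 30 of 1685 summit windows (1.78%, 1.25 to 2.53) and in 96 flanking windows (5.70%, 4.69 to 6.91). The ratio was 0.312, with 26 peaks holding it at the summit only and 92 in the flank only (p = 7.75e-10, two-sided exact McNemar test). Summit windows were richer in G and C, at 47.1% against 36.4%. Shuffled copies of the windows held TAATTA in 3.82% at summits and 10.19% in flanks, so base composition alone gave a difference in the same direction. Observed over shuffled shares were 0.466 at summits and 0.559 in flanks. The ratio of these was 0.834, for which no test was made. In the widest windows tried the ratio was 0.534, and for TAAT or ATTA in place of TAATTA it was 0.605 (exact p = 3.75e-53).

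Sequences that were more frequent at summits were rich in CpG. Of 2080 6-mers, 557 were more frequent and 425 less frequent at summits than in flanks. Among the 557, 416 had at least 4 G or C bases and 300 held a CpG, whereas 720 and 604 of all 2080 did. The 6-mer of lowest p, ACGCGC, was in 237 summit windows (14.1%) and 23 flanking windows (1.36%), a ratio of 10.3 (adjusted exact p = 3.02e-45, exact McNemar test). GAGCGC was also in 237 summit windows, against 26 flanks (ratio 9.12, adjusted exact p = 3.74e-42). Ratios were 9.67 for CGCGCC (adjusted exact p = 1.03e-37), 7.73 for AGCGCG (adjusted exact p = 1.28e-33) and 7.78 for GCGCGC (adjusted exact p = 1.86e-29). Against background windows with the same number of G and C bases, the 5 ratios were 5.92, 5.39, 3.08, 5.29 and 4.84 in the same order. Several of these 6-mers overlap each other in sequence, so they are not independent.

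**Figure D4:**
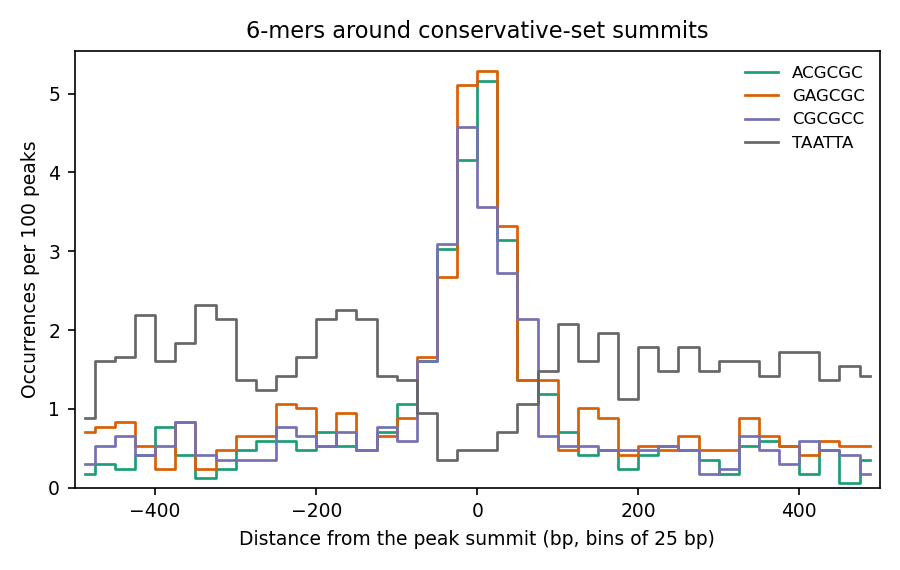
Occurrences per 100 conservative-set peaks (y axis) of ACGCGC, GAGCGC, CGCGCC and TAATTA by distance from the summit in bp (x axis, bins of 25 bp, both strands). Lines join the bins of each 6-mer over 1685 nuclear peaks. The first 3 rise at the summit and TAATTA falls there, as in the summit windows, where TAATTA was present in 1.78% against 5.70% of flanks.

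Peaks that passed the threshold in 1 replicate only differed in location from shared peaks. Their lower signal is tied to the threshold by which they were chosen, and location was not compared at equal signal. In replicate 1, 262 such peaks had a median signal of 62.2, against 100.3 for 904 shared peaks. They lay near a start less often (45.04% against 61.1%, adjusted exact p = 3.1e-05, two-sided Fisher's exact test) and on X more often (12.6% against 5.31%, adjusted exact p = 0.000438). In replicate 2, 442 such peaks had a median signal of 63.3 against 104.5, with 52.9% against 60.6% near a start (adjusted exact p = 0.012) and 10.9% against 5.27% on X (adjusted exact p = 0.000794). Shares near tRNA genes did not pass the test in either replicate (11.8% against 8.08% and 11.3% against 8.08%, adjusted exact p = 0.0652 for both). Against the other replicate's whole ranked list only 25 and 45 peaks were unmatched. The differences near a start were then -21.9 and -14.1 percentage points and no longer passed (adjusted exact p = 0.198 for both). Nor did the differences on X, which were 1.08 points in replicate 1 (adjusted exact p = 0.951) and 4.12 in replicate 2 (adjusted exact p = 0.493). In replicate 1 the unmatched peaks of highest signal were nearest to F58G1.7 (136), B0205.9 (135), the threonyl-tRNA synthetase gene tars-1 (116.9), F55D12.2 (67.3) and R07H5.16 (67.2). In replicate 2 they were nearest to VY10G11R.1 (252), ctns-1 (181), tbc-9 (125), efa-6 (110.1) and Y75B8A.31 (100.9). The conservative set holds a peak over the tars-1 interval, with a signal of 221. The unmatched efa-6 peak of replicate 2 (chromosome IV, 12621410 to 12621561) lies close beside a conservative peak (12621713 to 12622036, signal 1469). That conservative peak passed the threshold in both replicates, so the unmatched one may not be a separate site.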

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

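In this part, the test of starts beside small RNA genes, the test of soft-masked repeats, the test of intestine and muscle genes and the repeat of the list choice in matched draws were chosen only after the result was seen. The conservative set holds 22 peaks on the mitochondrial genome, which no result uses. They cover 47.8% of its 13794 bp, with a highest signal of 4054. The joint ranked list holds 73 nuclear peaks that pass the score minimum but are missing from the conservative set. Their median signal is 178, their highest is 3078 (chromosome X, 15810941 to 15811208), 18 lie on X and 1 lies near a start. They fall into 42 clusters, with a median of 94.6% soft-masked bases.

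Peaks at small non-coding RNA genes stood far above random positions. Reads shared between identical tRNA copies were tested on tRNA genes whose sequence occurs once in the genome, and 28 of 140 (20%, 14.2 to 27.4) had a peak, against a random mean of 0.831%. This share does not settle the question. A gene that differs from another by a single base counts as occurring once, and a summit within 250 bp can belong to a neighbouring gene. Genes with several copies had peaks more often (33.7%, Fisher's exact p = 0.00173), so shared reads stay open as a source. Protein-coding starts beside these genes were found at 24.9% of the peaks (20.4 to 30.1), too few to account for them. Signal that any antibody or tagged protein gives at such genes stays open, since no other library was analysed here, and no biological explanation was tested.

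6-mers more frequent at summits were recounted against other backgrounds. Against random positions with the same number of G and C bases, 41.8% of the 557 remained more frequent, where newly drawn flanks kept 91.0%. The number of G and C bases therefore does not account for the whole pattern. Composition beyond that number, such as CpG, was not matched. Without windows that hold a 31-mer present elsewhere, 67.9% remained, and without windows with a soft-masked base, 55.8% remained, in 1219 and 538 windows. Against windows at starts of genes without a peak, 604 6-mers were more frequent at summits. Those windows held 35.3% G and C, against 47.1% at summits. These values argue against a high G and C content shared by starts in general. Sequence that is open or CpG-rich at a part of the starts, whatever the factor, stays open because no other factor was analysed here. No biological explanation was tested.

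Peaks at the starts of broadly expressed gene lists were weighed over the 14 lists above other genes, which include the germline and small RNA lists. Heavy transcription of a gene whatever its tissue cannot be told apart from other sources, because transcription was not measured here. The counts known beforehand were 1.45% of 69 intestine and body wall muscle genes with a peak and 58.0% of ribosomal protein genes. The pooled share of these lists, 26.8%, was 2.26 times the highest among 1000 sets of genes matched by chromosome and number of starts nearby. It was 1.94 times the highest when the 14 lists of highest share were chosen anew in each matched draw of all 30. Closely packed starts are therefore argued against as the whole account, but they may add to the counts. With only the nearest gene per peak, 33 in place of 47 ribosomal protein genes and 6 in place of 14 chaperone genes had a peak. Starts that gather signal in many ChIP-seq libraries stay open, as no such library was analysed here, and no biological explanation was tested.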

How the results depend on the processing

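The tests at a global IDR of 0.001, of pairs thresholded in both replicates, of shuffled windows, of left-out peaks put back and of repeated 31-mers were chosen only after the result was seen. Of 93 alternative values of the main results, 84 were labelled the same. For tests this means the same direction and side of the threshold. For counts it means a change within a set fold, and for correlations a value inside the main interval. Of 568 other values, among them those for single lists, peaks and 6-mers, 535 were labelled the same. Another 27 no longer passed, 4 newly passed, and 2 no longer passed with an odds ratio below 1. Runs at an IDR of 0.01 are included, although they could not differ. Every alternative run was labelled the same for sharing between replicates, starts, X, non-coding classes, TAATTA and the number of 6-mers. TAATTA in shuffled windows (0.834) is the exception, as it had no test. Near starts the ratio ranged from 1.68 to 3.17, on X from 0.312 to 0.596, and for TAATTA from 0.222 to 0.834. Without replicate 1 or 2 the ratio on X was 0.512 or 0.499. The correlation of signal was 0.841 for pairs thresholded in both replicates, 0.742 for summits within 100 bp, 0.773 in the conservative set and 0.759 for values carried in the ranked list, against 0.685. The pairs differ by construction. With a 200 bp window, 585 genes had a peak and 8 lists were above other genes, as fewer summits count. The odds ratio was then 0 for the V-ATPase list, with 0 genes, and 0.947 for the cell cycle list, with 1 gene. Neither passed the test in either direction. Permutation within position classes called 9 lists, and the cause was not tested. Against the whole ranked list, peaks in 1 replicate only differed by -21.9 and -14.1 points near a start and no longer passed, with 25 and 45 peaks left. An IDR of 0.01 changes nothing, since it equals the authors' threshold. No paired analysis was possible because there is 1 group. Unknown depth limits all results, as peaks missing from a list were not shown to be absent.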

Other observations

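The gene lists, signal groups, chromosome middles and 10-mers in this part, and all of their tests, were chosen only after the data were seen. Motor protein genes carried peaks more often than other genes. Of 21 kinesin and dynein genes, 6 had a peak (28.6%, odds ratio 6.83, 2.17 to 18.7, adjusted exact p = 0.00766, Fisher's test over 10 lists), with signals of 1537 at klp-16 and 146.04 at klp-18, and from 103.8 to 136 at bmk-1, klp-19, dli-1 and zen-4. Aminoacyl-tRNA synthetases had 5 of 31 (adjusted exact p = 0.134), with 1221 at ears-2, 989 at mars-1, 362 at kars-1, 221 at tars-1 and 113 at aars-2. Mitochondrial ribosomal protein genes had 7 of 70, RNA polymerase subunits 3 of 21 and ubiquitin-conjugating enzymes 3 of 21 (adjusted exact p = 0.223 for each). RNA helicases had 1 of 12 (adjusted exact p = 0.621) and paired-pore potassium channels 2 of 46 (adjusted exact p = 1). No peak was found at 26 acetylcholine receptor subunits, 25 basic helix-loop-helix factors or 21 T-box factors (adjusted exact p = 0.57, 0.57 and 0.698).

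The peaks of highest signal differed in place and sequence from those of lowest signal. Of the 337 highest, 230 lay near a start, against 165 of the 337 lowest (adjusted exact p = 2.05e-06). Small RNA genes were beside 35 and 57 (adjusted exact p = 0.0242), 103 and 75 windows held a 31-mer present elsewhere in the genome (adjusted exact p = 0.0242) and 244 and 229 a soft-masked base (adjusted exact p = 0.238). From the highest to the lowest of 5 signal groups, shares beside small RNA genes were 10.4%, 18.7%, 22.6%, 21.96% and 16.9%, and shares with such a 31-mer were 30.6%, 22.8%, 32.05%, 30.6% and 22.3%, neither with a steady trend. GAGCGC was in 26.4% and 8.01% of the windows, without a test. The 10-mer GGCCCCACGA was in 27 of the 337 highest windows, in 12 of the other 1348 and in 1 of 1685 flanks. Of its 110 genomic copies, 44 (40%) lay in a peak, the largest share among the 10-mers most frequent in the highest windows. Several of these 10-mers overlap each other in sequence, so they are not independent. CCCCACGAAA was also in 27 of the 337, with 21.4% of its genomic copies in a peak, and CCACGAAAAG in 25, with 10.4%. On chromosome V, 176 of 250 peaks (70.4%) were in the middle of the chromosome, against 53.6% of starts (adjusted exact p = 5.31e-07). Over all chromosomes the shares were 57.5% and 55.9% (adjusted exact p = 0.296). On X, 74 of 276 tRNA genes had a peak (26.8%), against 113 of 336 on autosomes (33.6%, exact p = 0.0778). Adding the 73 left-out peaks, most of whose sequence is soft-masked, gave a ratio of 0.596 on X.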
